A study of Mus musculus with 12 samples.

How the data were processed

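Expression was measured in TSC2-/- mouse embryonic fibroblasts on 12 Affymetrix MOE430 v2 arrays, 3 in each of 4 groups, which the series design text calls biological triplicates. Cells received vehicle (DMSO) or 20 nM rapamycin for 14 h, or were infected for 10 h with adenovirus carrying GFP or PGC-1alpha and harvested 14 h later. Groups and replicate numbers were taken from the sample labels. RNA was isolated with Trizol and labelled with biotin, per the labels' protocols.

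The deposited values are intensities per probe set. Per the series design text and the labels, the authors made them with RMA at its default settings in BioConductor 1.2, with the rapamycin and vehicle arrays in 1 batch and the PGC-1alpha and GFP arrays in another. RMA corrects background, applies quantile normalization across the arrays of a batch and summarises the probes of each set. The scale of the deposited intensity values is not given in the sources used here; the values run from 9.299 to 21072.4 with array medians near 79, so they were read as linear and turned into log2 here without a pseudocount. No detection calls were used, so a dim probe set cannot be told from background, and the number of arrays limits the precision. Quantile normalization makes the arrays of a batch nearly alike in distribution, so a change in the total amount of RNA per cell would not be seen, and every fold change is relative to the other probe sets. The batches hold different experiments, so levels were compared only inside a batch.

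The table holds 45101 probe sets. The 64 Affymetrix control probe sets were left out, and 45037 were tested with no filter on low values. Of these, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none listed there, and only the first kind was named. Symbols were updated through Entrez IDs to a RefSeq table of the GRCm38.p6 annotation, in which the IDs of 34741 probe sets were found; no coordinates were used. For each of 18193 genes, the probe set with the highest mean log2 value over the 12 arrays stood for the gene. Of these genes 9010 had more than 1 probe set. Among genes with at least 2 probe sets past the threshold, 173 of 2218 had probe sets changed in opposite directions with rapamycin and 6 of 95 with PGC-1alpha.

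Each comparison was fitted on its own 6 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and two-sided p-values were adjusted by Benjamini-Hochberg over the 45037 probe sets, with a threshold of 0.05. Errors given with log2 changes are limma's moderated standard errors (SE). A rise or fall is stated only for an adjusted p under that threshold. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 43 lists with measured members, and again with an estimated correlation and with fry. The correlation was estimated from the same few arrays, so a list that fails with it is not shown to be unchanged. Camera asks whether a list moved relative to all other genes. Fry asks whether the genes of a list changed at all, without setting them against other genes. Fisher's exact test, two-sided, was used for the overlap of gene calls, adjusted over 4 pairs of directions. The difference between the effects was the contrast of the changes in a limma fit of 4 group means over all 12 arrays. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the figures.

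The tests, 44 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists covered respiratory complexes I, II with III, IV and V and their union (OXPHOS), the tricarboxylic acid cycle, fatty acid oxidation, the mitochondrial ribosome, import, DNA expression and dynamics, PGC-1alpha targets from earlier work, antioxidant enzymes, glycolysis, HIF-1 targets, the pentose phosphate pathway, cholesterol and fatty acid synthesis, ATF4 targets, tRNA synthetases, the cytosolic ribosome, ribosome biogenesis, nucleotide synthesis, DNA replication, mitosis, lysosome, autophagy, FOXO targets with growth factor receptors, the unfolded protein response, heat shock, p53 targets, extracellular matrix, interferon response, inflammation, immediate early genes, gluconeogenesis and markers of skeletal muscle, brown fat, white fat, macrophages, endothelium, epithelium and neural cells. Of 1076 list memberships, 1004 were measured; the list of genes encoded by the mitochondrial genome had 0 measured members. The text could name, per comparison, the 10 genes with the largest rise and the 10 with the largest fall past the threshold whose treated arrays all lay beyond all control arrays, up to 4 members of each list past the threshold with the largest change plus the largest opposite one (where none passed, the 2 with the smallest p), and 24 fixed regulators of which 23 were measured; genes chosen otherwise are marked where they appear.

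On simulated data with the same arrays' levels and spread, the fit recovered 49.3% of probe sets changed by 0.25 on the log2 scale for rapamycin and 31.3% for PGC-1alpha, and 100% and 98.5% of those changed by 0.5, with 12 and 11 false calls among 45037. The simulation changed few probe sets, against 25.5% called with rapamycin, and drew each independently of the others. Recovery and false calls in the real data can therefore differ from these. Alternatives were other scalings (median centring, quantile normalization over 12 arrays), only the brighter 50% of probe sets, 1 fit over 12 arrays, an intensity trend in the prior, the replicate number as a block, stricter thresholds, other ways of choosing a gene's probe set, other list tests and leaving out each array in turn. Scaling on the bacterial spike controls, and removal of an axis of array-to-array differences, were added after seeing the data. These spikes are hybridization controls, so scaling on them does not measure RNA per cell.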

Results

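The arrays compared TSC2-/- fibroblasts, cells that lack a brake on the growth-promoting kinase mTOR, in 2 experiments of 6 arrays each: the mTOR inhibitor rapamycin against vehicle, and adenoviral PGC-1alpha, a transcriptional coactivator known for raising mitochondrial genes, against GFP. Per the series title, the study linked the mTOR pathway to mitochondrial gene expression through YY1 and PGC-1alpha. Median intensity lay between 77.5 and 81 on every array, and log2 values of arrays of the same group correlated at 0.997 or more across probe sets, which are not independent replicates. The spread between arrays of a group was widest among the GFP arrays, where the SD of differences between array pairs reached 0.17, against at most 0.14 among rapamycin, 0.12 among vehicle and 0.11 among PGC-1alpha arrays. By that SD, GFP replicate 3 lay nearer to each PGC-1alpha array (0.142 to 0.151) than to GFP replicates 1 and 2 (0.155 and 0.167). Limma's p-values measure the spread between arrays of the same group. The 3'/5' signal ratio of the Gapdh controls was 0.820 ± 0.011 (SD, n = 3) with rapamycin and 0.849 ± 0.011 (SD, n = 3) with vehicle, without overlap. It was 0.899 ± 0.006 (SD, n = 3) with PGC-1alpha and 0.875 ± 0.008 (SD, n = 3) with GFP, again without overlap. The other controls overlapped. The beta-actin ratio was 1.31 ± 0.01 with rapamycin, 1.31 ± 0.02 with vehicle, 1.32 ± 0.01 with PGC-1alpha and 1.28 ± 0.03 with GFP (SD, n = 3 each). That of the transferrin receptor was 3.95 ± 0.20 with rapamycin, 3.67 ± 0.19 with vehicle, 3.21 ± 0.21 with PGC-1alpha and 2.98 ± 0.03 with GFP (SD, n = 3 each).

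The rapamycin comparison asked which transcripts respond when mTOR is inhibited in cells without TSC2. By camera at its preset correlation, rapamycin lowered ATF4 targets and genes of ribosome biogenesis, nucleotide synthesis, DNA replication, mitosis and glycolysis, and raised inflammatory and extracellular matrix genes. Of the mitochondrial lists, the mitochondrial ribosome, protein import, mitochondrial DNA expression and the tricarboxylic acid cycle fell. None of these lists passed with an estimated correlation, where the smallest rapamycin value was adjusted p = 0.173. That setting called no list in either comparison, not even DNA replication, where all 26 members were lower and 25 of them fell. The correlation was estimated from the few arrays of each comparison (0.33 for DNA replication), and the power at such values was not measured. Failing there therefore does not show that a list stayed unchanged. With fry 26 of the 43 rapamycin lists passed, among them all 21 that camera called. Fry does not set a list against other genes, so it answers another question than camera. OXPHOS genes went both ways, with 13 raised and 19 lowered, although with spike scaling 1 rose and 35 fell. Among the probe sets brightest for their gene over the 12 arrays, the greatest changes were a 3.68-fold rise of Lcn2, a secreted iron-siderophore binding protein, and a 3.67-fold fall of Ddit4, a stress-induced inhibitor of mTOR signalling. The 4 dimmer probe sets of Klhl24 rose more than Lcn2, by 1.91 to 2.32 on the log2 scale. In total 5168 probe sets rose and 6301 fell, 25.5% of those tested, and among genes 2061 rose and 3275 fell. Changes of at least 1.5-fold numbered 546 and 810. Scaled on the bacterial spike controls, which were higher on the rapamycin arrays, every change was lower by 0.16 on the log2 scale. Then 1653 probe sets rose and 13971 fell, and 10.6% rather than 45.1% of the calls were rises. Changes are given relative to the authors' normalization.

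After Lcn2, the top rises by the brightest probe set, with all rapamycin arrays above all vehicle arrays, were Klhl24, Crebrf, Il6, Vnn1, Calcoco1, Ctla2a, Akap5, Bckdha and Tcp11l2, with log2 changes from 1.68 for Klhl24 to 1.26 for Tcp11l2. Il6, an inflammatory cytokine, rose 3.04-fold (SE 0.07 on the log2 scale, adjusted p = 3.7e-08, n = 3 arrays per group). Bckdha encodes a subunit of the branched-chain keto acid dehydrogenase. The falls after Ddit4 were Psph (-1.44), Cdc6 (-1.40), Bnip3 (-1.38), Slc16a3 (-1.37), Cth (-1.34), Ak4 (-1.32), Srm (-1.23), Lrr1 (-1.21) and Psat1 (-1.21). Probe sets of a gene differed for Calcoco1 (1 of 2 rose), Ak4 (3 of 5 fell) and Lrr1 (1 of 3 fell, while the brightest on these 6 arrays was at -0.13). Psph and Psat1 make serine, Cth makes cysteine, Srm makes spermidine, Cdc6 licenses replication origins and Slc16a3 exports lactate.

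Growth and synthesis lists fell broadly. Of 35 ribosome biogenesis genes 33 fell, with a median of -0.61, and 0 rose. Dkc1, which modifies ribosomal RNA, fell by 1.17 and Rrp12 by 1.11 on the log2 scale. The cytosolic ribosomal proteins themselves did not pass camera, with 6 raised and 3 lowered of 46 (0 raised and 8 lowered with spike scaling). Among them were Rpl37 at 0.29 and Rps27l at -0.30. With fry the list passed as raised (adjusted p = 0.011). Of 27 ATF4 targets 24 fell (median -0.56), among them Shmt2 (-1.15), the mitochondrial serine hydroxymethyltransferase. Atf4 itself fell by 0.56 (SE 0.05, adjusted p = 6.0e-06; 2 of its 3 probe sets fell). Of 18 tRNA synthetases 17 fell, with Farsb at -0.85, and Qars rose by 0.40. Of 22 nucleotide synthesis genes 18 fell, including Tk1 (-1.15) and Pfas (-0.97). DNA replication had 25 of 26 members lowered (Ccne2 -0.96, Gins1 -0.87) and mitosis 25 of 27 (Mybl2 -1.10, Aurka -0.86). All these falls passed camera at its preset correlation, with adjusted p from 3.5e-10 for tRNA synthetases to 3.1e-20 for ribosome biogenesis. None did with an estimated correlation, where adjusted p = 0.355 to 0.368.

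Lists of glucose metabolism and fatty acid synthesis also fell. Of 16 glycolysis genes 12 fell, with a median of -0.56, among them Pfkp (-1.13) and Pfkl (-0.97), subunits of phosphofructokinase, and the glucose transporter Slc2a1 (-0.89). Of 17 HIF-1 targets 13 fell, among them Egln3 (-1.20) besides Ddit4 and Bnip3. The pentose phosphate pathway had 5 of 8 members lowered, led by Prps1 (-0.62), and fatty acid synthesis 10 of 15, with Elovl6 at -0.67 and Fasn at -0.43. These lists passed camera (adjusted p = 6.5e-09, 9.9e-09, 0.0027 and 0.00013). With an estimated correlation the adjusted p-values were 0.368, 0.355, 0.376 and 0.410. Cholesterol synthesis did not pass, with 3 raised and 4 lowered of 21 (0 and 8 with spike scaling), such as Tm7sf2 at 0.33 and Sc5d at -0.31.

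Mitochondrial lists differed in their camera calls under rapamycin, although no test set one list against another. Of 76 mitochondrial ribosomal protein genes 54 fell and 2 rose (median -0.33, camera adjusted p = 6.9e-16; adjusted p = 0.368 with an estimated correlation), with Mrps22 at -0.84 and Mrpl12 at -0.75. Import had 20 of 24 lowered (median -0.43, adjusted p = 9.9e-09; adjusted p = 0.355 with an estimated correlation), with Timm8a1 at -1.09 and the chaperone Hspd1 at -0.63. The tricarboxylic acid cycle had 12 of 20 lowered and 1 raised (median -0.17, adjusted p = 0.00052; adjusted p = 0.571 with an estimated correlation). Of 10000 draws of genes of like brightness, 777 had a median as low, against 0 for the mitochondrial ribosome and 7048 for OXPHOS. The draws took genes independently, whereas the estimated correlation within these lists was 0.40 to 0.55, so these counts are not chance frequencies. Idh3a, a subunit of isocitrate dehydrogenase, fell by 0.71 (SE 0.06, adjusted p = 3.2e-06) from a mean intensity of 1798 to 1097, with 3 of its 4 probe sets lowered. Mitochondrial DNA expression had 10 of 18 lowered (adjusted p = 0.0025; adjusted p = 0.376 with an estimated correlation), with Gfm1 at -0.66 and Tfam, the mitochondrial transcription factor, at -0.36. Of 75 OXPHOS genes 19 fell, 13 rose and 43 did neither (22 lowered and 14 raised when adjusted over the list alone). The median was -0.03 and the list did not pass (adjusted p = 0.923, and 0.986 with an estimated correlation). Cyc1, cytochrome c1, fell by 0.63 (SE 0.06), Atp5g1 by 0.49 and Sdhd by 0.42, while Cox7a2l, a factor of respiratory supercomplexes, rose by 0.70 (SE 0.05) and Atp5e by 0.30. With spike scaling 35 OXPHOS genes fell and 1 rose, with a median of -0.19, and the list again did not pass (adjusted p = 0.760). That says nothing on a fall, since camera tests a list relative to other genes and this scaling lowers every change alike. With quantile normalization over 12 arrays the median was 0.02, with 21 raised and 18 lowered. Fatty acid oxidation did not pass either, with 5 raised (Decr1 0.42, Ech1 0.39) and 3 lowered of 24 (2 and 8 with spike scaling), although it passed with quantile normalization over 12 arrays (9 raised and 1 lowered, adjusted p = 0.011). Nor did mitochondrial dynamics pass (3 raised and 3 lowered of 10, Pink1 0.82). PGC-1alpha targets from earlier work did not pass camera (3 raised and 9 lowered of 28, or 0 and 15 with spike scaling, Hk2 -0.77). Nor did antioxidant enzymes (3 raised and 8 lowered of 18, Hmox1 -0.58). With fry both lists passed as lowered (adjusted p = 0.028 and 0.040). Fry also called complexes II and III with cytochrome c lowered (adjusted p = 0.025) and complex IV raised (adjusted p = 0.028). Camera called neither of these complex lists (adjusted p = 0.114 and 0.131). With spike scaling the complex IV median of 0.07 turned to -0.09, with 1 raised and 3 lowered.

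Among regulators, Pprc1, a relative of PGC-1alpha, fell by 0.52 (SE 0.06, adjusted p = 1.9e-05) and Nrf1 by 0.40 (SE 0.06, adjusted p = 0.00014). Of the 4 Nrf1 probe sets 2 fell, and the others were at -0.12 and 0.06. All 5 Ppargc1a probe sets were dim here. The brightest on these 6 arrays fell by 0.31 (SE 0.06, adjusted p = 0.0022), from a mean log2 value of 5.99 to 5.68, and 2 dimmer ones fell by 0.30 and 0.35. The one that stands for the gene, the brightest over 12 arrays, did not pass (log2 change -0.13, SE 0.07, adjusted p = 0.188), with mean intensities of 40.6 and 37.1, nor did the fifth (-0.10). The brightest Yy1 probe set did not pass (-0.11, adjusted p = 0.164) whereas the 3 others fell by 0.43 to 0.56. Esrra did not pass (-0.04, SE 0.05, adjusted p = 0.714). Rictor rose by 0.37, although only 2 of its 5 probe sets rose and the others were at 0.03 to 0.16. Tsc2 fell by 0.40. The Tsc2 probe set read intensities of 182 to 278 in the rapamycin and vehicle arrays of these Tsc2-null cells. Without wild-type arrays its level checks nothing about the deletion.

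Lists that rose with rapamycin were fewer. Of 25 inflammatory genes 17 rose and 0 fell (median 0.28, camera adjusted p = 6.5e-09; adjusted p = 0.173 with an estimated correlation), among them Ptgs2 (0.88) and Tnfaip3 (0.87). Extracellular matrix had 17 of 31 raised, led by the growth factor Ccn2 (1.15) and Ccn1 (0.85), with Col6a3 lowered (-0.47; adjusted p = 2.9e-08, and adjusted p = 0.368 with an estimated correlation). Autophagy had 12 of 25 raised, with Nbr1 at 0.86 and Map1lc3b at 0.63, and 4 lowered (adjusted p = 0.00059; adjusted p = 0.571 with an estimated correlation), and its median of 0.14 turned to -0.02 with spike scaling, where 6 rose and 5 fell and the list also passed (adjusted p = 2.0e-05). FOXO targets and growth factor receptors had 12 of 24 raised, such as Ccng2 (0.72) and Pdgfrb (0.67), with Sesn3 lowered (-0.68; adjusted p = 0.00052, and adjusted p = 0.355 with an estimated correlation). The unfolded protein response had 12 of 20 lowered with Dnajb11 at -0.68, although Dnajb9 rose by 0.82 (adjusted p = 0.0021; adjusted p = 0.533 with an estimated correlation). Heat shock had 5 of 11 lowered with Hsph1 at -0.80 (adjusted p = 0.032; adjusted p = 0.483 with an estimated correlation), a call lost without rapamycin replicate 1 (adjusted p = 0.065) and with quantile normalization over 12 arrays (adjusted p = 0.078). Epithelial markers passed narrowly (4 raised, such as the keratins Krt18 at 0.56 and Krt7 at 0.52, and 1 lowered of 15; adjusted p = 0.048, and adjusted p = 0.355 with an estimated correlation). That call was lost without vehicle replicate 2 (adjusted p = 0.086) or rapamycin replicate 1 (adjusted p = 0.090), and with quantile normalization over 12 arrays (adjusted p = 0.094). With spike scaling the list median of 0.07 turned to -0.09 and the list passed (adjusted p = 0.028). The median over all probe sets was then -0.16. So the passes of epithelial markers and autophagy there are relative to other genes and are not falls. With spike scaling members raised and lowered numbered 10 and 3 for inflammation, 7 and 2 for extracellular matrix, and 7 and 6 for FOXO targets. These lists passed there too, again relative to other genes. Camera at the preset correlation also called up to 17 lists in splits of the same arrays that called 0 probe sets. Those splits mixed rapamycin and vehicle arrays and so kept part of the treatment difference. Hence 17 is not a count expected by chance.

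**Figure D1:**
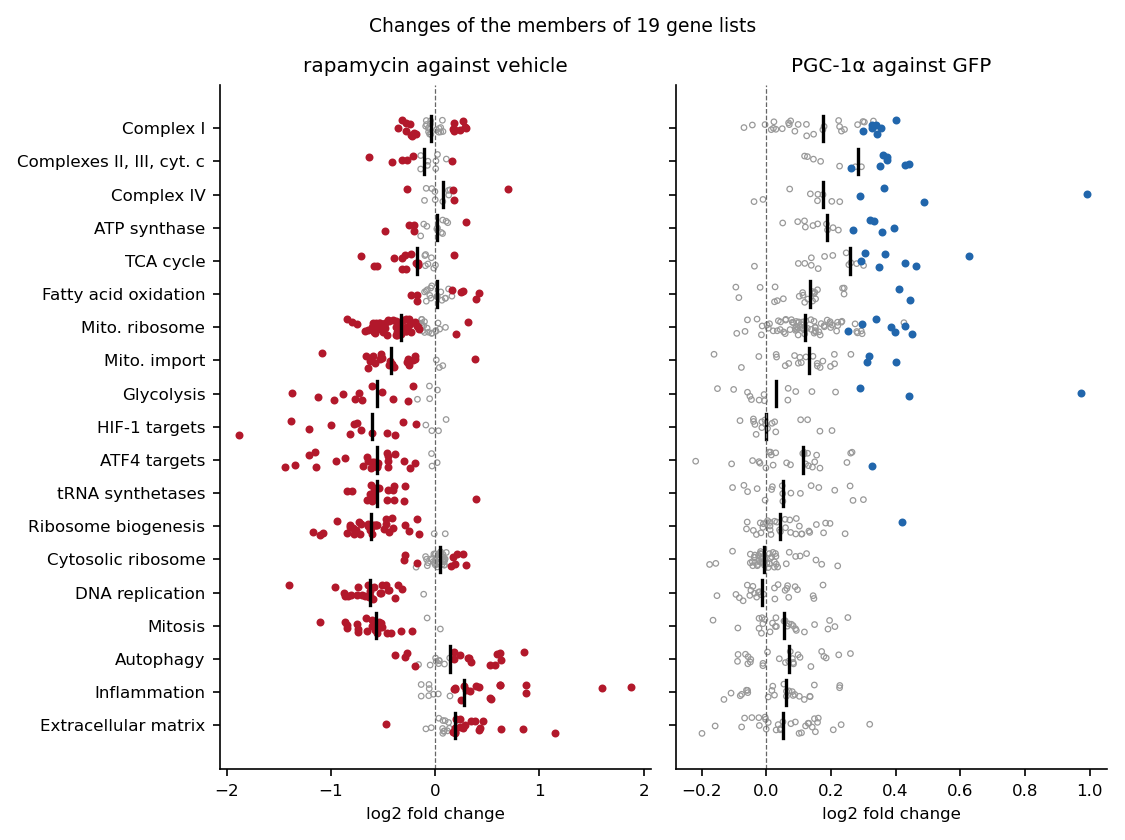
Log2 fold changes (horizontal axes, scaled separately in the panels) of the members of 19 gene lists for rapamycin against vehicle (left) and PGC-1alpha against GFP (right); each point is a gene, filled where its adjusted p was under 0.05, and black bars are list medians. With rapamycin the ribosome biogenesis median was -0.61 and the OXPHOS complexes lay between -0.11 and 0.07 (all below 0 with spike scaling), whereas with PGC-1alpha the complexes lay between 0.18 and 0.28.

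The PGC-1alpha comparison asked what the coactivator changes by itself. Ppargc1a rose 26.8-fold, from a mean intensity of 87.3 to 2339 (log2 change 4.74, SE 0.09, adjusted p = 3.6e-11, n = 3 arrays per group). Of 75 OXPHOS genes 23 rose, as did 7 of 20 tricarboxylic acid cycle genes, and 0 of either fell. In total 449 probe sets rose and 430 fell, 1.95% of those tested, and among genes 257 rose and 108 fell. Changes of at least 1.5-fold numbered 34 and 58. These counts moved with single arrays. Without GFP replicate 3 they were 1957 and 880. Without PGC-1alpha replicate 3 they were 117 and 166, without GFP replicate 2 113 and 190, and without PGC-1alpha replicate 2 144 and 187. Without GFP replicate 1 they were 120 and 283, and without PGC-1alpha replicate 1 122 rose. Scaled on the spike controls, 250 rose and 38 fell, 86.8% rises against 51.1%, with every change higher by 0.14. The spike controls of these groups overlapped (10.51 to 10.80 with PGC-1alpha and 10.67 to 10.91 with GFP, two-sided exact permutation p = 0.3). With that scaling 10 OXPHOS and 4 tricarboxylic acid cycle genes rose.

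By the brightest probe set, the top rises after Ppargc1a were Chchd10, a mitochondrial intermembrane space protein, at 4.01-fold (log2 change 2.00, SE 0.08, adjusted p = 8.9e-08), Mcrip2 (1.03), the cytochrome oxidase subunit Cox7a1 (0.99), Pfkp (0.97), the lactate dehydrogenase subunit Ldhb (0.88), Trp53inp2 (0.71), Amn (0.66), Nudt19 (0.66) and Comtd1 (0.66). Cox7a1 stayed dim, with a mean intensity of 37.1 with GFP and 73.9 with PGC-1alpha. The top falls were Malat1, a nuclear long non-coding RNA, at -1.03 (SE 0.21, adjusted p = 0.031), then the RNA helicase Ddx6 (-0.87), Taok1 (-0.80), the BMP antagonist Grem1 (-0.79), Bpnt2 (-0.65), Hspa1a (-0.65), Nbeal1 (-0.64), the cohesin loader Nipbl (-0.60), Nrk (-0.60) and Ccdc59 (-0.58). Several of these falls rest on part of the probe sets. For Taok1 1 of 7 fell (the others at -0.23 to 0.10), for Bpnt2 1 of 3 (-0.03 and 0.23), for Nipbl 1 of 5 (0.01 to 0.15) and for Nrk 1 of 3 (-0.25 and 0.15). For Malat1 4 of 7 fell, for Ddx6 and Nbeal1 2 of 4, while 2 of 3 rose for Pfkp and 1 of 2 for Trp53inp2. Of these 20 genes only Malat1 lost its call when an array was left out, with adjusted p = 0.051 without GFP replicate 1, 0.163 without GFP replicate 2, 0.107 without PGC-1alpha replicate 2 and 0.087 without PGC-1alpha replicate 3. Of the 5 Ppargc1a probe sets only the brightest rose, and the 4 others lay between -0.13 and 0.03.

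OXPHOS genes had a median rise of 0.20 (camera adjusted p = 4.5e-29; adjusted p = 0.721 with an estimated correlation), and 44 rose when adjusted over the list alone. All 4 complexes passed camera, with 7 of 33 raised in complex I, 7 of 14 in complexes II and III with cytochrome c, 4 of 13 in complex IV and 5 of 15 in ATP synthase. With an estimated correlation adjusted p = 0.721 to 0.733. Cox5a rose by 0.49 (SE 0.07, adjusted p = 0.0034), Uqcrfs1, the Rieske protein, by 0.44 and Uqcrc1 by 0.43. With Cox7a1 these were the 4 of the 23 that passed whichever array was left out. The count raised was 4 without PGC-1alpha replicate 3, 5 without GFP replicate 2, 6 without GFP replicate 1 or PGC-1alpha replicate 1, 9 without PGC-1alpha replicate 2 and 38 without GFP replicate 3. The median OXPHOS level relative to the GFP mean was 0.15 to 0.25 on the PGC-1alpha arrays and -0.09 to 0.09 on the GFP arrays. The brightest Cycs probe set did not pass (0.13, adjusted p = 0.508), while 2 others for cytochrome c rose by 0.38 and 0.41.

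The tricarboxylic acid cycle had a median of 0.26 (adjusted p = 8.6e-17; adjusted p = 0.721 with an estimated correlation). Idh3a rose by 0.63 (SE 0.06, adjusted p = 0.00040) and Mdh1 by 0.46 (SE 0.07, adjusted p = 0.0035). These were the only raised genes of the list that passed with any array left out. Its levels were 0.20 to 0.31 on the PGC-1alpha arrays and at most 0.10 on the GFP arrays. Smaller counts stood behind fatty acid oxidation (2 of 24, Hadhb 0.41; adjusted p = 1.0e-05, and adjusted p = 0.733 with an estimated correlation), import (3 of 24; adjusted p = 1.9e-06, and adjusted p = 0.733 with an estimated correlation) and the mitochondrial ribosome (7 of 76, Mrpl12 0.43; adjusted p = 7.1e-15, and adjusted p = 0.733 with an estimated correlation). For the mitochondrial ribosome the groups overlapped: GFP replicate 3 had a list median of 0.11 and the PGC-1alpha arrays 0.10 to 0.16. Of its raised genes only Mrpl12 passed whichever array was left out. The nuclear receptor Esrra, a partner of PGC-1alpha, rose by 0.36 (SE 0.06, adjusted p = 0.011), a call lost without GFP replicate 1 (adjusted p = 0.059) or PGC-1alpha replicate 2 (adjusted p = 0.071), and its other probe set was at 0.14. Nrf1 (-0.01), Gabpa (0.08), Tfam (0.09), Yy1 (0.07) and Ppargc1b (-0.06) did not pass, each with SE 0.06 to 0.08.

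**Figure D2:**
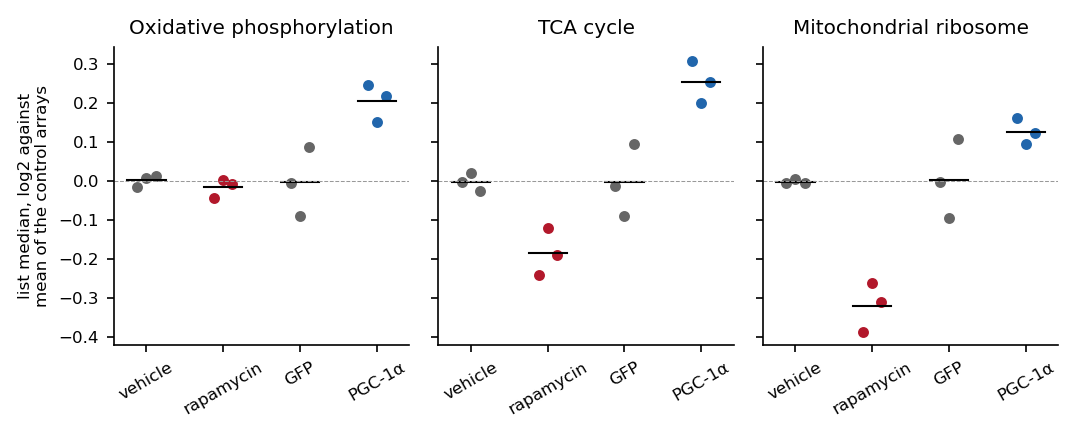
Median log2 value of a list's genes on each array (vertical axis, relative to the mean of the control arrays of the same experiment) for OXPHOS, the tricarboxylic acid cycle and the mitochondrial ribosome; points are the 3 arrays of a group and bars their mean. OXPHOS lay at 0.15 to 0.25 with PGC-1alpha and at most 0.09 with GFP, while for the mitochondrial ribosome a GFP array at 0.11 lay within the PGC-1alpha arrays.

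Of the remaining lists, PGC-1alpha targets from earlier work (3 of 28), mitochondrial DNA expression (2 raised and Tfb2m lowered by 0.55 of 18), mitochondrial dynamics (0 of 10), antioxidant enzymes (2 of 18, Sod2 0.46 and Txn2 0.45), fatty acid synthesis (0 of 15), ATF4 targets (1 of 27), tRNA synthetases (0 of 18), ribosome biogenesis (1 of 35), lysosome (0 of 33) and extracellular matrix (0 of 31) passed camera in the upward direction, with adjusted p from 8.6e-05 to 0.048. With an estimated correlation adjusted p = 0.721 to 0.733. With quantile normalization over 12 arrays only PGC-1alpha targets and mitochondrial DNA expression among these 10 passed, the 8 others having adjusted p = 0.077 to 0.624. Then FOXO targets (median -0.02, adjusted p = 0.049), the unfolded protein response (-0.05, adjusted p = 0.019) and heat shock (-0.05, adjusted p = 0.026) passed. With spike scaling mitochondrial dynamics, fatty acid synthesis, tRNA synthetases, lysosome and extracellular matrix did not pass (adjusted p = 0.0503 to 0.091). Glycolysis (0.0035), heat shock (0.020) and brown fat (2.7e-33) did. The median over all probe sets was then 0.135, above those of heat shock (0.083) and brown fat (0.122). So neither of these 2 medians rose beyond that common shift. Brown fat holds the overexpressed Ppargc1a, and 2 of its 13 members rose. With arrays centred on their medians extracellular matrix did not pass (adjusted p = 0.056). Leaving out an array ended the call of 7 of the 19 lists that passed. It ended that of mitochondrial dynamics without GFP replicate 2 (adjusted p = 0.450), GFP replicate 1 (0.065) or PGC-1alpha replicate 1 (0.144), and that of antioxidant enzymes without GFP replicate 1 (0.069), GFP replicate 2 (0.079) or PGC-1alpha replicate 1 (0.067). Fatty acid synthesis lost its call without GFP replicate 1 (0.059) or 2 (0.086), and tRNA synthetases without GFP replicate 2 (0.406) or PGC-1alpha replicate 1 (0.0502). Ribosome biogenesis lost its call without GFP replicate 2 (0.231) or PGC-1alpha replicate 1 (0.209), and lysosome without GFP replicate 1 (0.105), GFP replicate 2 (0.393) or PGC-1alpha replicate 3 (0.062). Extracellular matrix lost its call without GFP replicate 1 (0.253), GFP replicate 2 (0.196), PGC-1alpha replicate 1 (0.145) or PGC-1alpha replicate 3 (0.051). Glycolysis did not pass (adjusted p = 0.057, 3 of 16 raised), although Pfkp rose. Neither did the cell type markers, gluconeogenesis (0 of 9 changed), DNA replication (0 of 26), mitosis (0 of 27), interferon response (0 of 29) or inflammation (0 of 25). With fry none of the 19 passed, and only the brown fat list, which holds Ppargc1a, did. Splits of the arrays that called 0 probe sets gave up to 30 lists with camera, more than the 19 seen. Those splits mixed arrays of both groups and so kept part of the treatment difference. Their list counts are therefore not those expected by chance.

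Both comparisons were then set side by side, since the series title joins the pathways; they share no array. Genes lowered by rapamycin and raised by PGC-1alpha numbered 139, against 46.3 expected from independent lists (odds ratio 5.56, 95% interval 4.30 to 7.19, Fisher's exact test adjusted p = 9.8e-39), 54.1% of the genes PGC-1alpha raised. With the brighter 50% of probe sets alone the shared genes numbered 206 against 104 expected, with a lower odds ratio of 3.43 (95% interval 2.76 to 4.27), and at 1.5-fold 5 genes gave 16.0 (4.41 to 49.2). Those raised by rapamycin and lowered by PGC-1alpha numbered 52, against 12.2 expected (odds ratio 7.43, adjusted p = 2.7e-21). By contrast, 24 genes rose in both (29.1 expected, adjusted p = 0.372) and 14 fell in both (19.4 expected, adjusted p = 0.278). Fisher's test takes genes as independent, which they are not, so its p-values and intervals do not measure the spread between arrays. The count of 139 was 38 without PGC-1alpha replicate 1 or 3, 49 without PGC-1alpha replicate 2, 40 without GFP replicate 1 or 2 and 569 without GFP replicate 3. The shared genes included 11 of 75 OXPHOS, 6 of 20 tricarboxylic acid cycle and 7 of 76 mitochondrial ribosome genes. Of these only Cox5a, Uqcrfs1, Uqcrc1, Idh3a and Mrpl12 kept both calls whichever array was left out. Chchd10 was at -0.27 with rapamycin and 2.00 with PGC-1alpha, Mcrip2 at -0.85 and 1.03, Pfkp at -1.13 and 0.97, Idh3a at -0.71 and 0.63, Mrpl12 at -0.75 and 0.43, and Cox5a at -0.27 and 0.49. Of the 2 Chchd10 probe sets only 1 fell with rapamycin, and the other was at -0.12. In the opposite direction Malat1 was at 1.08 and -1.03, Ddx6 at 0.30 and -0.87, and Taok1 at 0.31 and -0.80, although of the 7 Taok1 probe sets 3 rose and 1 fell with rapamycin. Cox7a1 rose with PGC-1alpha and did not pass with rapamycin (difference -0.99, SE 0.15, adjusted p = 7.1e-05). As this probe set is dim, a fall with rapamycin could be missed. Across all 18193 genes, which are not independent replicates, the log2 changes correlated at r = -0.23.

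**Figure D3:**
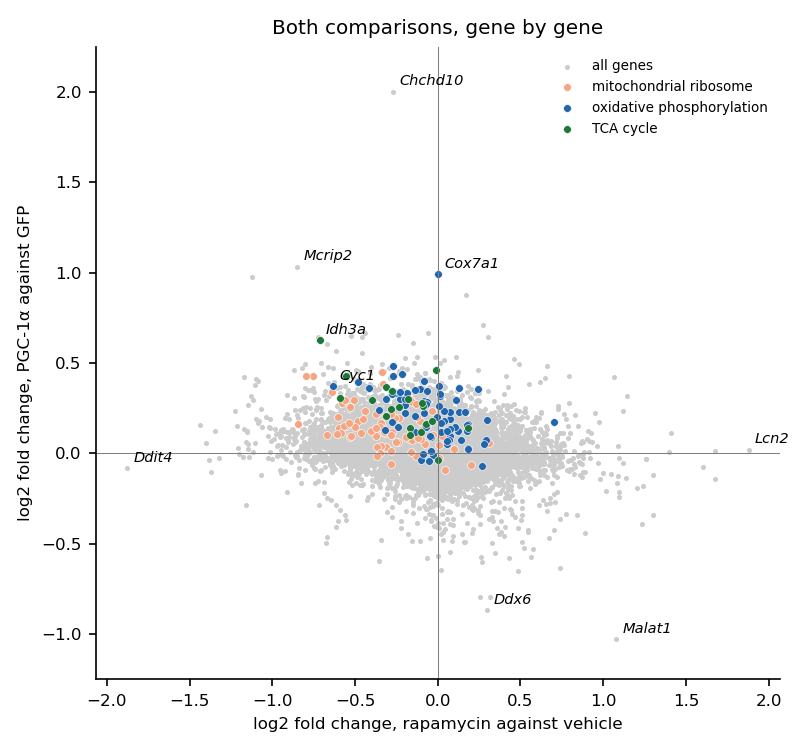
Log2 fold change with rapamycin (horizontal axis) against that with PGC-1alpha (vertical axis) for each gene, with OXPHOS, tricarboxylic acid cycle and mitochondrial ribosome genes in colour; Ppargc1a, at 4.74 on the vertical axis, lies outside the plot. Idh3a lies at -0.71 and 0.63, and the correlation across all genes is -0.23.

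The difference between the effects was tested directly over the 12 arrays. It passed for 9304 probe sets, with the rapamycin effect the higher for 3919 and the lower for 5385. OXPHOS genes as a list moved lower with rapamycin than with PGC-1alpha (median difference -0.20, camera adjusted p = 2.5e-06; adjusted p = 0.651 with an estimated correlation), as did the tricarboxylic acid cycle (-0.48, adjusted p = 3.4e-09; adjusted p = 0.30 with an estimated correlation) and the mitochondrial ribosome (-0.44, adjusted p = 4.3e-20; adjusted p = 0.30 with an estimated correlation). For Idh3a the difference was -1.34 (SE 0.09, adjusted p = 1.3e-08), for Cyc1 -1.01 (SE 0.09, adjusted p = 3.0e-07) and for Tfam -0.45 (SE 0.09, adjusted p = 0.0015).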

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

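The tests of the array-to-array axis and of the choice of probe set, and that of spike scaling, were chosen after the result was seen. The bacterial spike controls, left out of the comparisons, averaged 0.16 higher on the log2 scale on the rapamycin arrays (10.87 to 11.08) than on the vehicle arrays (10.78 to 10.86), with no overlap, two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow.

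With PGC-1alpha 23 of 75 OXPHOS genes rose and the list median was 0.20 (camera adjusted p = 4.5e-29, adjusted p = 0.721 with an estimated correlation and 0.110 with fry), while GFP replicates 2 and 3 differed from each other by a comparable amount in the same genes. A shift common to all genes of that brightness is argued against. The OXPHOS median exceeded that of brightness-matched genes by 0.18, and 0 of 10000 matched draws reached it. The draws took genes independently, so that count is not a chance frequency. With the leading axis of array differences, taken from the rapamycin and vehicle arrays, removed, the median was 0.200 against 0.203. The spread of the GFP arrays narrowed from -0.09 and 0.09 to -0.07 and 0.06. These values argue against that axis as the whole cause. It held 17.3% of the variance among GFP arrays and 2.5% among PGC-1alpha arrays, so other array differences stay open. The 10 splits of the 6 arrays are too few to exclude chance: the real split, 1 of 10, gave 0.203 and the highest other 0.156. A response to PGC-1alpha stays a hypothesis.

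OXPHOS genes went both ways with rapamycin while the mitochondrial ribosome and other lists fell by camera at its preset correlation, none of them with an estimated correlation (smallest adjusted p = 0.173 over all rapamycin lists, and 0.368 for the mitochondrial ribosome). Compression of bright signals is argued against as the whole cause: the 47 members of the 16 lowered lists as bright as the middle of the OXPHOS genes had a median of -0.31, against -0.05 for OXPHOS genes in that range, but all 378 members had -0.43, so partial compression stays open. The choice of probe set is also argued against, since the mean over all probe sets of each gene gave a median of 0.00078. Scaling cannot be told apart from the treatment, because with spike scaling the OXPHOS median was -0.19 and no value here decides which scaling holds; the gap between OXPHOS and the lowered lists does not depend on it. As to chance, 4 of the 10 splits gave an OXPHOS median as far from 0 (0.0315 in the real split, 0.0399 at most in the others).

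Rapamycin and PGC-1alpha moved genes in opposite directions. Removing the axis of the other experiment left an odds ratio of 4.65 for genes lowered by rapamycin and raised by PGC-1alpha. Within 10 bins of equal brightness the median correlation of the changes was -0.19. So neither that axis nor a brightness-dependent scale accounts for all of the opposite movement. The axes held 15.2% of the variance within rapamycin, 17.3% within GFP, 2.7% within vehicle and 2.5% within PGC-1alpha arrays. Their removal therefore tests only a small part of the array differences. Splits of the arrays say nothing of chance for the 139 shared genes: wrong splits of either experiment called 0 genes, so that of 100 draws only the real splits (1 draw) and both with the sign turned (52 genes, the highest other) could share any. For differing probe sets 1 of 100 drawn splits reached 9304 (the highest other 6198). The 82 draws wrong in both experiments called 0, while 6 draws that kept the rapamycin arrays in place gave 5572 to 6198. No draw paired the real rapamycin split with the PGC-1alpha split turned in sign. The count therefore speaks only against both groupings being arbitrary at once. It cannot exclude chance for either experiment alone and says nothing of opposite directions. Other array differences that act on both experiments stay open. Among them is RNA quality, since the Gapdh 3'/5' ratio also moved in opposite directions without overlap. It was 0.849 with vehicle and 0.820 with rapamycin, and 0.875 with GFP and 0.899 with PGC-1alpha. The other controls overlapped and did not move in opposite directions. The mean transferrin receptor ratio was 3.95 with rapamycin against 3.67 with vehicle, and 3.21 with PGC-1alpha against 2.98 with GFP. That of beta-actin was 1.31 with both rapamycin and vehicle, and 1.32 with PGC-1alpha against 1.28 with GFP. A shared pathway may add to the overlap as a hypothesis.

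Of the 10 splits within each experiment, too few to exclude chance, 1 gave as many called probe sets as the real one (11469 for rapamycin and 879 for PGC-1alpha, 0 in every other split). For lists called by camera, 1 of 10 splits reached the 21 of rapamycin (highest other 17), and 4 of 10 reached the 19 of PGC-1alpha (highest other 30, with GFP replicate 3 beside PGC-1alpha replicates 1 and 3), which points to a structure among these arrays. The other splits mixed arrays of both groups and kept part of the treatment difference, so their list counts are not those of chance.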

How the results depend on the processing

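Alternatives were compared with the values above; spike scaling and removal of the other experiment's axis were chosen after seeing the data, and the cause of a move was not tested unless given. Probe sets raised and lowered by PGC-1alpha were 807 and 678 in 1 fit over 12 arrays, where the shared genes were 233. They were 110 and 170 at an adjusted p under 0.01 (34 shared genes, rapamycin raised 3311). They were 34 and 58 at 1.5-fold (5 shared genes, rapamycin 546 and 810), the last from a stricter threshold. Spike scaling gave 1653 and 13971 for rapamycin and 250 and 38 for PGC-1alpha. With an estimated correlation the OXPHOS rise of 0.20 with PGC-1alpha no longer passed (adjusted p = 0.721) and 0 rather than 40 lists passed over both comparisons. As no list passed with it, that setting cannot tell lists that moved from lists that did not. With fry the OXPHOS rise did not pass (adjusted p = 0.110) and 27 lists passed, 21 of them rapamycin lists that camera called. Leaving out an array gave 113 to 1957 probe sets raised and 166 to 880 lowered by PGC-1alpha, 38 to 569 shared genes, and no change of direction or side for OXPHOS. Replicate numbers did not pair the arrays. Same-number deviations correlated at -0.05, 0.07 and 0.005 for rapamycin and -0.13, 0.23 and -0.01 for PGC-1alpha. With the number as a block 5128 and 6243 probe sets changed with rapamycin, 436 and 395 with PGC-1alpha, with 140 shared genes. Among named genes, leaving out an array ended a call 83 times with rapamycin and 124 times with PGC-1alpha and reversed none. Dim probe sets, such as those for Ppargc1a on the rapamycin and vehicle arrays, limit what small changes can show.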

Other observations

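Other lists under rapamycin, none of which passed camera with the authors' normalization, held members that moved apart. Of 21 immediate early genes 10 rose and 5 fell (adjusted p = 0.131). With spike scaling, chosen after the data were seen, 4 rose and 6 fell and the list passed (adjusted p = 0.029). Its median of -0.005 then lay above the -0.16 over all probe sets, so the pass is relative to other genes and not a fall. The list held the transcription factor Egr1 at 0.48 and Fosl1 at -0.92, Atf3 at -0.56 and Jun at -0.51. Of 16 p53 targets 3 rose and 9 fell, with Trp53inp1 at 0.71, Sesn2 at -0.45 and the cell cycle inhibitor Cdkn1a at -0.31. Of 33 lysosomal genes 8 rose and 5 fell (2 and 13 with spike scaling), with the hydrolases Naglu at 0.49 and Ctsd at 0.41 and Atp6v1c1, a subunit of the proton pump, at -0.43. Interferon-stimulated genes split evenly, 5 up and 5 down of 29 (3 and 13 with spike scaling), with Gbp2 at 0.80 and Ifit1 at -0.50.

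Among markers of other cell types, the epithelial list passed camera narrowly with rapamycin (4 raised and 1 lowered of 15, adjusted p = 0.048, and adjusted p = 0.355 with an estimated correlation) and the lists that follow did not. Mef2c fell by 0.32 among 25 skeletal muscle genes (0 raised, 3 lowered), Lpl fell by 0.31 among 14 white fat genes (1 raised, 3 lowered), and 2 of 18 macrophage, 1 of 13 brown fat, 2 of 15 neural and 0 of 14 endothelial genes passed. With spike scaling 8 muscle, 6 white fat, 6 endothelial and 5 neural genes were lowered. Of 9 gluconeogenic genes 1 rose and 3 fell, and none of these 4 passed with every array left out in turn. With PGC-1alpha 0 members of the muscle, white fat, macrophage, endothelial, epithelial and neural lists passed; of the brown fat list Ppargc1a and Cox7a1 did.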
